A study of Mus musculus with 12 samples.

How the data were processed

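RNA was sequenced from 12 libraries of sorted 2D2 TH17 cells (1000 cells per library per the labels), prepared by a modified SMART-Seq2 protocol with Nextera XT and read on a NextSeq instrument. The deposited table holds raw counts per gene symbol for each library, which the authors made, per their processing notes, with STAR 2.7.11a and featureCounts of Subread 1.6.4 on mm10. No normalisation had been applied to the deposited counts, and a gene length column gives merged exon lengths in bases. The annotation release and the STAR and featureCounts settings are not given in the sources used here. Of 55291 symbols, 53180 (96.2%) matched 1 gene of GENCODE M21 (GRCm38), and 99.0% of these had the same merged exon length, so coordinates were taken from that release. All samples of the table were used and none was left out.

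Libraries were grouped by genotype and sorted subset as labelled: WT CXCR6+ (n = 2), WT SLAMF6+ (n = 2), DKO CXCR6+ (n = 4) and DKO SLAMF6+ (n = 4). Total counts ran from 1347044 to 9451700 per library, and 17998 to 40916 genes had counts. Mitochondrial transcripts took 1.66% to 3.72% and ribosomal protein genes 8.24% to 15.0% of the counts. Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15, by group), which left 24195, libraries were scaled by TMM, and a fit of the 4 groups over all 12 libraries was tested by the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single genes come from this edgeR test unless another tool is named. The comparisons were CXCR6+ over SLAMF6+ in each genotype, DKO over WT in each subset, and the difference of the subset effects (interaction). The standard error of a log2 change is its size divided by the square root of F. In 39 gene lists fixed before the data were examined, direction was tested with camera (limma 3.58.1, preset correlation between genes 0.01, adjusted over the lists of a comparison), and again with the correlation estimated. Camera compares the genes of a list with all other tested genes. A list called lower or higher is so relative to them, whatever the sign of its median. List members were also adjusted over the list alone.

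Genes to be named were chosen by a rule set before the data were examined: Il17a, Il17f, Cxcr6 and Slamf6 always; the up to 8 higher and 8 lower genes with the largest change among those past the threshold, with at least 10 CPM in the higher group and no overlap between the groups, leaving out predicted genes, receptor segments, mitochondrial and ribosomal protein genes and sex-linked genes; up to 4 passing members of each list; up to 2 members of a list with none, as values only; and genes in which 1 library stood apart from its group. Genes named outside this rule are said to have been chosen after their values were seen. Background was measured as counts on 1469 olfactory and vomeronasal receptor genes per kb of their 5393.4 kb of exons. A group with no counts was given a bound from a floor of 3 counts per library.

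The alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, limma's voom with sample quality weights, no filter on low counts, a filter of 5 CPM in 2 libraries, a fit of only the compared libraries, leaving out receptor segment, mitochondrial, ribosomal protein and sex-linked genes, the replicate number as a block in the subset comparisons, camera with the correlation estimated, and leaving out each library in turn. A group left with 1 library was assumed to vary like the others. Chosen after the data were seen were the log2 background density as a covariate, the 7 libraries with at most 1 CPM per kb of background, a mean of at least 10 CPM, the covariate combined with that filter or with the block, and the lists without Cxcr6 and Slamf6. Of the WT CXCR6+ libraries, the 7 low-background libraries hold only replicate 2.

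Counts were simulated with the study's own group sizes and dispersions, and 200 genes with a mean of at least 10 CPM were changed. The test was tried on these counts. For a 4-fold change it recovered 71% of genes between the DKO subsets, 23% between the WT subsets, 52% between genotypes in CXCR6+ cells and 40% in SLAMF6+ cells, and for a 16-fold change 96%, 85%, 89% and 87%. Of the 188, 111, 154 and 135 genes called, 21, 3, 13 and 8 were false. With the covariate, on counts to which each library's background was added, 89% and 58% of 4-fold changes were recovered between the DKO and the WT subsets. Of the 202 and 157 genes called there, 15 and 4 were false. The counts simulated for the test without the covariate held no such background. On simulated lists camera called the 1 list that was shifted and 0 of 20 unchanged ones. The simulated genes varied independently, so this does not bear on false list calls where the genes of a list are correlated.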

Results

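The cells were 2D2 T cells, whose transgenic receptor recognises myelin oligodendrocyte glycoprotein. They had been polarised to TH17, transferred into RAG2-/- hosts and sorted from the central nervous system at peak disease as CD4+ cells, CXCR6+ or SLAMF6+. The cells were wild type (WT) or lacked Il17a and Il17f (double knockout, DKO). There were 2 WT CXCR6+, 2 WT SLAMF6+, 4 DKO CXCR6+ and 4 DKO SLAMF6+ libraries. The labels do not say that replicates are separate animals, so the p-values measure the spread between these samples, which may be partly technical. Levels are TMM-normalised CPM (counts scaled to library size), given as mean ± SD over the n libraries of a group, and log2 changes are given ± SE.

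Il17a, a targeted cytokine gene on chromosome 1 (20730905 to 20734496 on GRCm38/mm10, GENCODE M21), gave 509 and 4090 counts in the WT CXCR6+ libraries and 130 and 437 counts in the WT SLAMF6+ libraries. The 8 DKO libraries gave 1 to 28 counts. Il17a averaged 579 ± 505 CPM in WT CXCR6+ (n = 2), 174 ± 113 CPM in WT SLAMF6+ (n = 2), 2.45 ± 1.72 CPM in DKO CXCR6+ (n = 4) and 2.99 ± 2.33 CPM in DKO SLAMF6+ (n = 4). It fell by 7.998 ± 0.71 on the log2 scale from WT to DKO in CXCR6+ cells (adjusted p = 4.54e-07) and by 5.84 ± 0.66 in SLAMF6+ cells (adjusted p = 6.32e-05). The genotypes did not overlap in either subset. Background counts, measured on genes silent in T cells, would give a gene of this length 0.219 to 3.75 CPM before scaling in the DKO libraries. Before scaling, Il17a lay above its library's background in 3 of 4 DKO CXCR6+ and 3 of 4 DKO SLAMF6+ libraries. Its mean excess over the 4 libraries of each group was 0.817 and 1.91 CPM. Il17f, the other targeted gene and a partner of Il17a in IL-17 heterodimers (20777146 to 20790617 on chromosome 1), reached 21.4 and 50.3 CPM in the WT CXCR6+ libraries. It gave 2 and 0 counts in the WT SLAMF6+ libraries and 0 to 29 counts in the DKO libraries, where background alone would give 2.18 to 16.1 counts. Its change in CXCR6+ cells, -4.38 ± 1.41, did not pass the threshold (adjusted p = 1) with all libraries. It passed with background density as a covariate (-6.55), and was -4.86 without WT CXCR6+ replicate 1, which leaves 1 library in that group. In SLAMF6+ cells Il17f lay near background in both genotypes, so no genotype difference was detectable at this depth.

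**Figure D1:**
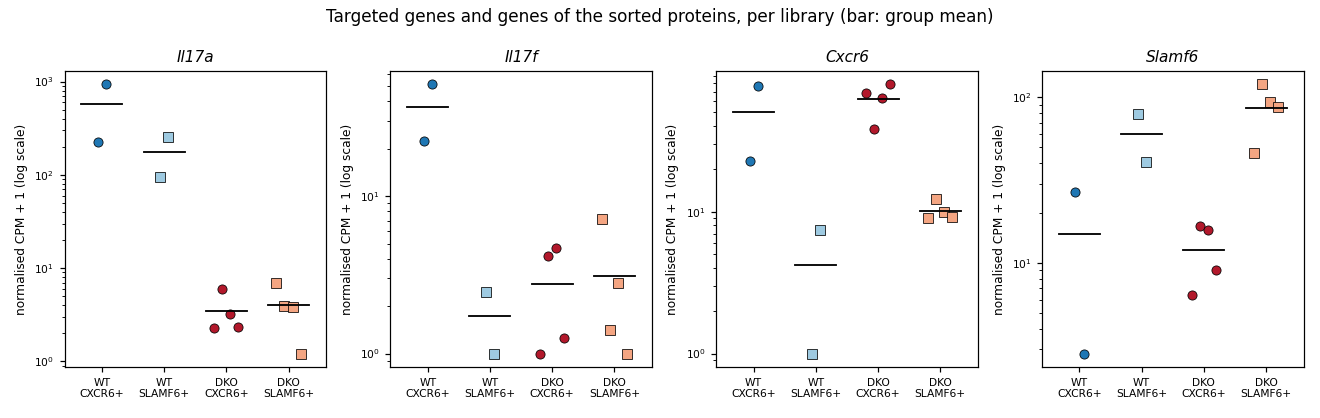
Normalised CPM plus 1 on a log axis for Il17a, Il17f, Cxcr6 and Slamf6 in each of the 12 libraries, by group (points: libraries, bar: group mean). Il17a lay between 93.8 and 936 CPM in the WT libraries and between 0.213 and 5.93 CPM in the DKO libraries.

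Olfactory and vomeronasal receptor genes, which serve smell and are silent in T cells, carried counts in every library at densities that differed between replicates. The 1469 receptor genes held 0.0775 CPM per kb of exon in WT CXCR6+ replicate 2 and 3.20 CPM per kb in DKO CXCR6+ replicate 4. Spread evenly over all exons, these densities would amount to 1.02% and 42.0% of the library. The density was tightly related to the first principal component of the libraries, which held 46.0% of the variance: Pearson's r was -0.953 and Spearman's rho -0.944 over the 12 libraries, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. Without the 2 libraries farthest from the median density r was -0.945, and this was the only relation of the kind computed. The component was computed over all tested genes, receptor genes among them, so part of the relation is built in. How large that part is was not tested. The groups overlapped in density in all 4 comparisons. Mean log2 differences were 0.72 between the DKO subsets and 1.36 between genotypes in CXCR6+ cells. The exact two-sided permutation p was 1 between the WT subsets (smallest possible 0.333), 0.543 between the DKO subsets (smallest possible 0.0286), 0.467 between genotypes in CXCR6+ cells and 1 in SLAMF6+ cells (smallest possible 0.0667), and all 4 were 1 after Benjamini-Hochberg adjustment. Adding the log2 density to the model as a covariate, a choice made after the data were seen, lowered the common dispersion across genes from 0.748 to 0.239.

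**Figure D2:**
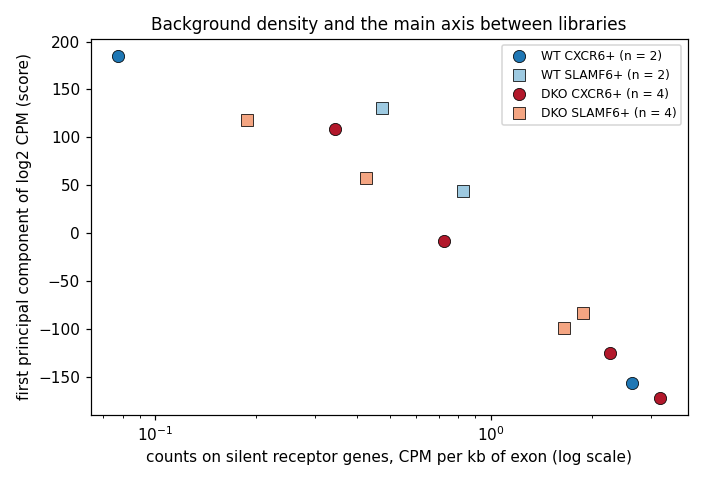
Density of counts on silent receptor genes (CPM per kb of exon, log axis) against the first principal component score of each of the 12 libraries, by group. Libraries lined up by density, from 0.0775 to 3.20 CPM per kb.

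Cxcr6, the receptor for CXCL16 used in the sort, was higher in DKO CXCR6+ libraries (61.2 ± 17.2 CPM, n = 4) than in DKO SLAMF6+ libraries (9.11 ± 1.52 CPM, n = 4), a log2 change of 2.76 ± 0.51 (adjusted p = 0.0256). Slamf6, the other sort marker and a homophilic receptor of stem-like T cells, was lower (11.02 ± 5.09 against 85.2 ± 30.4 CPM), a change of -2.97 ± 0.53 (adjusted p = 0.0188). In WT cells the same genes differed by 3.85 ± 0.82 and -2.14 ± 0.74 without passing the threshold in edgeR's fit of the 4 groups (adjusted p = 0.298 and 0.625). With all libraries, Cxcr6 passed with DESeq2, no filter, the replicate block or the background covariate (3.51). Slamf6 passed with the covariate (-2.49). Without WT CXCR6+ replicate 1, a library with 2.64 CPM per kb of background, Cxcr6 and Slamf6 changed by 4.49 and -4.95, with 1 library left in that group. Before scaling, Slamf6 read 30.5 CPM in that library, where background would give a gene of its exon length 28.6 CPM. Leaving out 1 DKO library moved Cxcr6 between 2.62 and 2.93 and Slamf6 between -3.18 and -2.74. Cxcr6 no longer passed in 7 of these 8 fits (all but that without DKO CXCR6+ replicate 4) and Slamf6 in 5 (without DKO CXCR6+ replicate 3 or 6, or DKO SLAMF6+ replicate 4, 5 or 6). Slamf6 also missed the threshold with RLE scaling (-2.79).

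Il2, the cytokine that drives T cell growth, averaged 145 ± 67.2 CPM in DKO SLAMF6+ libraries and 23.8 ± 9.44 CPM in DKO CXCR6+ libraries (n = 4 each). It fell by 2.59 ± 0.44 in CXCR6+ cells (adjusted p = 0.0182). Pou2af1, a lymphoid coactivator of octamer factors, fell by 3.27 ± 0.58 (3.47 ± 1.95 against 34.98 ± 17.4 CPM, adjusted p = 0.0182). Irf8, an interferon regulatory factor, fell by 2.17 ± 0.38 (20.2 ± 5.97 against 91.4 ± 44.7 CPM, adjusted p = 0.0182). Pou2af1 and Irf8 are expressed in B cells too, and the antibody genes Ighm (-4.31) and Igkc (-5.03) fell in the same comparison. Ccl17, a ligand of CCR4, was near zero in DKO CXCR6+ cells (0.936 ± 0.937 CPM) and reached 33.9 ± 13.6 CPM in DKO SLAMF6+ cells, a change of -5.14 ± 0.91 (adjusted p = 0.0182). On the CXCR6+ side, Il1r2, the decoy receptor for IL-1, rose by 2.05 ± 0.38 (126 ± 47.5 against 30.2 ± 6.53 CPM, adjusted p = 0.0236). Rbp1, a carrier of retinol, rose by 2.62 ± 0.49 (58.3 ± 24.4 against 9.47 ± 5.91 CPM, adjusted p = 0.0245).

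Of 24195 genes tested between DKO CXCR6+ and DKO SLAMF6+ cells, 16 changed, 3 higher and 13 lower in CXCR6+ cells. In all 16 the 4 libraries of each subset did not overlap. Chance gives this for 2.86% of unselected genes, but these 16 were selected on the same libraries, so it is no separate support. The others that fell were Ighm and Igkc, which encode antibody chains, Prss2, a trypsinogen gene that lies inside the T cell receptor beta locus on chromosome 6 (41521787 to 41525079), Jaml, an adhesion molecule, and Ccdc28b, a cilium-linked gene, with Pou2f2, also a B cell gene, Dgkk and Hivep3 chosen after their values were seen. Prss2 changed by -2.79 ± 0.40 (adjusted p = 0.00297), Jaml by -2.79 ± 0.54 and Ccdc28b by -2.35 ± 0.45 (adjusted p = 0.0339 each). Ighm changed by -4.31 ± 0.59 (adjusted p = 0.0026) and Igkc by -5.03 ± 0.89 (adjusted p = 0.0182). The count rested on single libraries: it was 1 without DKO SLAMF6+ replicate 4, 2 without DKO CXCR6+ replicate 6 or DKO SLAMF6+ replicate 6, 7 without DKO CXCR6+ replicate 3, and 8 without DKO CXCR6+ replicate 5 or DKO SLAMF6+ replicate 5. It was 10 without DKO CXCR6+ replicate 4 and 17 without DKO SLAMF6+ replicate 3. DESeq2 called 126 genes, limma's voom 32, and edgeR with the background covariate 207 (105 higher and 102 lower), which included all 16. Of these 207, the subsets did not overlap in 105. The median log2 change of all genes was 0.11, and 0.22 with RLE scaling, under which 14 genes passed (5 higher and 9 lower).

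**Figure D3:**
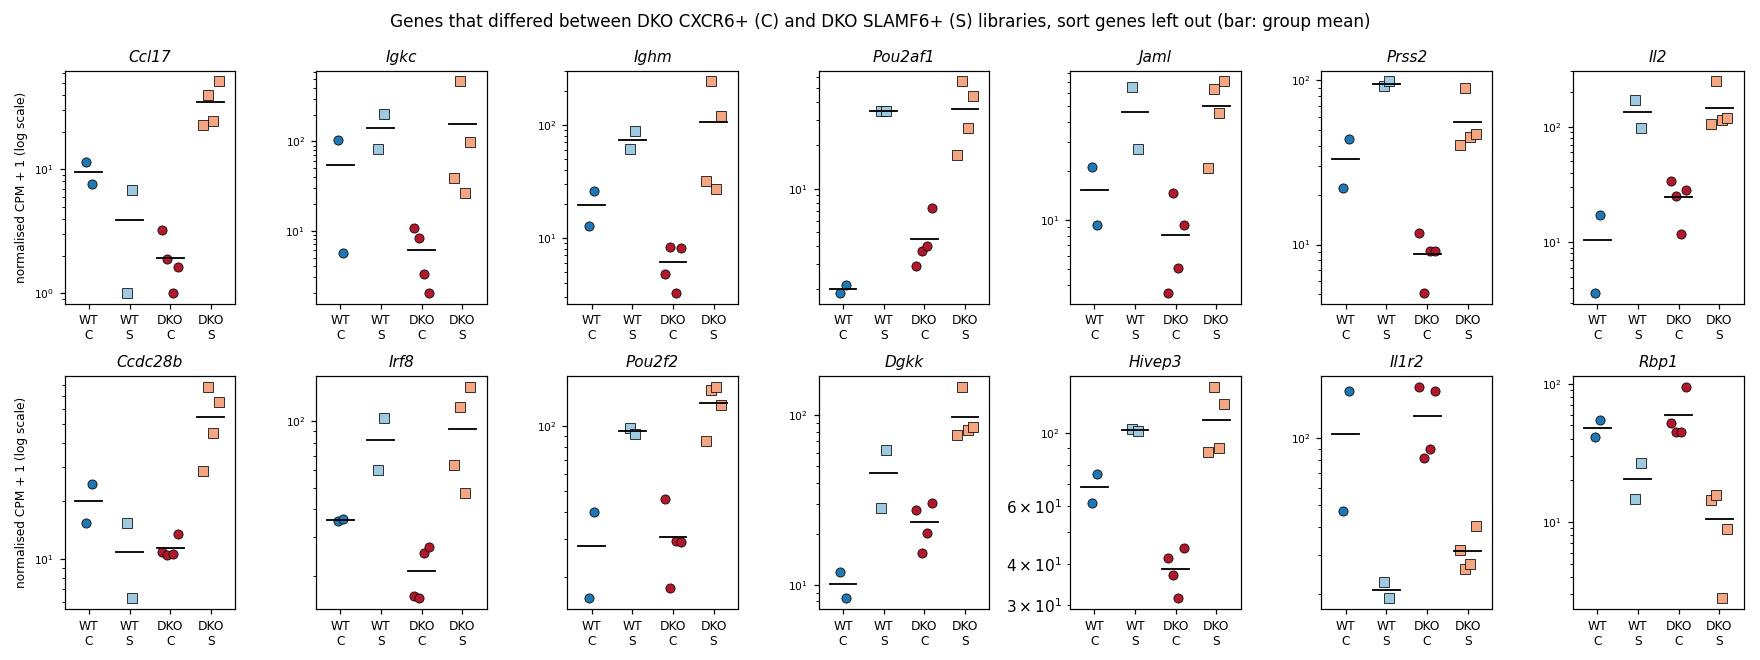
Normalised CPM plus 1 on a log axis, in each library, of 14 of the 16 genes that differed between DKO CXCR6+ and DKO SLAMF6+ cells (the sort genes are left out), with WT libraries beside them (points: libraries, bar: group mean). Il2 averaged 145 CPM in DKO SLAMF6+ and 133 CPM in WT SLAMF6+ libraries, against 23.8 and 9.44 CPM in the CXCR6+ libraries.

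Stem-like and memory T cell genes were lower in DKO CXCR6+ cells as a list: 15 of 20 tested genes had a negative change, with a median of -0.48 (camera adjusted p = 3.6e-13; adjusted p = 0.0895 with an estimated correlation). Slamf6, on which the cells were sorted, was the 1 member that passed over all genes. Without it the list was still called (14 of 19 negative, median -0.44, adjusted p = 1.03e-09; adjusted p = 0.156 with an estimated correlation). Adjusted over the list alone 7 passed, among them Tcf7 (-1.28 ± 0.37), the transcription factor that keeps T cells stem-like, Foxp1 (-1.38 ± 0.32), a quiescence factor, Ltb (-1.31 ± 0.34), which encodes lymphotoxin beta, and Izumo1r (-1.40 ± 0.37), the folate receptor 4 gene, all 4 chosen after their values were seen. Immediate early and dissociation genes, which respond within minutes to a stimulus or to handling, were lower in 15 of 17 (median -0.61, adjusted p = 1.15e-07; adjusted p = 0.409 with an estimated correlation). None passed over all genes, and Jund (-1.14 ± 0.33) and Egr1 (-1.16 ± 0.35) passed adjusted over the list alone. Type I interferon response genes were lower in 18 of 22 (median -0.36, adjusted p = 0.000173), a call that held with an estimated correlation (adjusted p = 0.0497), with no member past the threshold on its own, Ifi27l2a included (-1.27 ± 0.42).

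TH1-type genes were lower in 11 of 14 (median -0.59, adjusted p = 2.64e-05; adjusted p = 0.108 with an estimated correlation). Tbx21, the TH1 master regulator, passed adjusted over the list alone (-1.36 ± 0.37), while Ifng averaged 123 ± 94.6 CPM in DKO CXCR6+ and 279 ± 168 CPM in DKO SLAMF6+ cells without passing (-1.18 ± 0.43). Chemokine genes were lower in 6 of 9 (median -0.93, adjusted p = 0.000233; adjusted p = 0.108 with an estimated correlation). None of the list's members passed over all genes (Ccl17, which did, is not on the list) and 5 passed adjusted over the list alone: Ccl22 (-1.82 ± 0.43), Ccl1 (-1.94 ± 0.61), Xcl1 (-3.81 ± 1.23) and Ccl20 (-2.64 ± 1.09) lower, and Cxcl3, a neutrophil attractant, higher (2.13 ± 0.85). T cell cytokine genes were lower in 18 of 29 (median -0.32, adjusted p = 0.000264; adjusted p = 0.517 with an estimated correlation), with Il2 past the threshold over all genes and 4 adjusted over the list alone, where Ltb and Tnfsf14 (-1.49 ± 0.46) were lower and Il24 (1.45 ± 0.42) was higher. B cell and plasma cell markers were lower in 6 of 8 (median -2.07, adjusted p = 4.78e-08), which held with an estimated correlation (adjusted p = 0.0497). Ighm and Igkc passed over all genes, Jchain (-2.02 ± 0.70) passed with them adjusted over the list alone, and the B cell receptor gene Cd79a stayed at 0 to 2.13 CPM before scaling in every DKO library. These 7 lists, the stem-like to the B cell list, passed in each of the 8 fits that left out 1 DKO library. The cytokine list was lost with the background covariate, and the TH1-type, chemokine and cytokine lists were lost with the replicate block and the covariate together.

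The TH17 program was higher in DKO CXCR6+ cells in 13 of 21 (median 0.26, adjusted p = 0.0123; adjusted p = 0.637 with an estimated correlation), with no member past the threshold. It was not called without DKO CXCR6+ replicate 3 (adjusted p = 0.279) or 6 (adjusted p = 0.067) or DKO SLAMF6+ replicate 5 (adjusted p = 0.0989). With the background covariate 2 members rose, Il23r (1.32), the IL-23 receptor chain, and Tmem176a (1.63), an ion channel gene. The T cell receptor signalling response was lower (12 of 20, median -0.22, adjusted p = 0.000108; adjusted p = 0.776 with an estimated correlation), with Irf8 past the threshold over all genes and 3 adjusted over the list alone. The pathogenic TH17 signature (11 of 22 positive, median -0.03; 3 adjusted over the list alone, Lrmp, Lag3 and Tbx21) and TFH-type genes (4 of 11 positive, median -0.02; Izumo1r adjusted over the list alone) were called lower (adjusted p = 0.00455 each; adjusted p = 0.714 and 0.409 with an estimated correlation). T cell identity genes were called lower (median -0.12, adjusted p = 0.0123, and 0.867 with an estimated correlation), and their median was 0.08 with the covariate. Over 14 alternatives their direction reversed in 2. These 4 lists all lost the call without DKO SLAMF6+ replicate 6 or DKO CXCR6+ replicate 4 (adjusted p from 0.0629 to 0.874). The pathogenic signature was also lost without DKO CXCR6+ replicate 5 (adjusted p = 0.0776), and T cell identity without DKO SLAMF6+ replicate 4 (0.128) or DKO CXCR6+ replicate 5 (0.519). All 4 were also lost with the background covariate, and all but the TFH list in the low-background libraries.

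**Figure D4:**
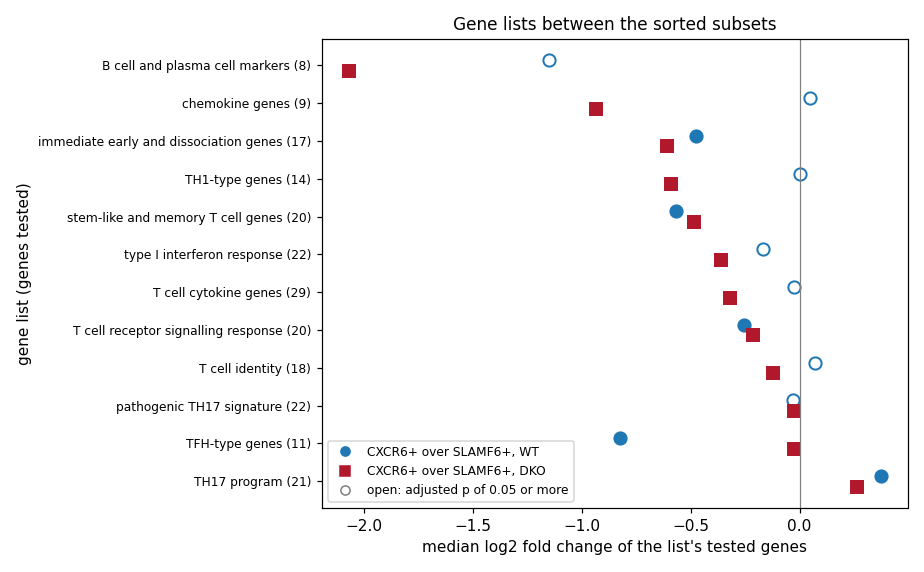
Median log2 fold change, CXCR6+ over SLAMF6+, of the tested genes of each list that was called in at least 1 genotype (circles: WT, squares: DKO; filled where the camera adjusted p passed). Stem-like and memory genes lay at -0.57 in WT and -0.48 in DKO cells.

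Tissue residency and effector genes were not called as a list between the DKO subsets (11 of 19 positive, median 0.15, adjusted p = 0.534), but 4 passed adjusted over the list alone: Cxcr6, Ccr2 (1.12 ± 0.41), a chemokine receptor of inflamed tissue, and Id2 (1.22 ± 0.43), an effector transcription factor, were higher and Crtam (-1.40 ± 0.35) was lower. Among chemokine receptors and trafficking genes Ccr1, a receptor for CCL3 and CCL5, passed with Cxcr6 adjusted over the list alone (1.74 ± 0.39). Glycolysis genes were positive in 14 of 20 (median 0.22, adjusted p = 0.0946). With the background covariate they passed as a list, and Bnip3 (1.44), Pgk1 (1.11), Gapdh (0.89) and Eno1 (0.87) rose, enzymes of sugar breakdown apart from Bnip3, a hypoxia-response gene. The subsets overlapped in Pgk1, Gapdh and Eno1. Of the markers of other cell types, Ermn, a myelin gene, passed adjusted over the list alone (1.24 ± 0.33; 119 ± 46.9 against 50.4 ± 10.3 CPM).

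In WT cells, Il2 averaged 9.44 ± 9.64 CPM in CXCR6+ and 133 ± 51.1 CPM in SLAMF6+ libraries (-3.74 ± 0.66), and Pou2af1 1.01 ± 0.191 and 33.8 ± 0.131 CPM (-4.99 ± 0.93). This was the same direction as in DKO cells, without passing (adjusted p = 0.0854 and 0.103; both chosen after their values were seen, n = 2 per group). Il17a was 1.73 ± 0.70 higher in WT CXCR6+ cells and Il17f 5.65 ± 2.07 higher (adjusted p = 0.625 each). The WT subsets overlapped in Il17a. Over the alternatives Il17a ranged from 0.348 to 2.65 and Il17f was 4.62 or more. Il1r1, the signalling receptor for IL-1 and chosen after its values were seen, read 19.3 ± 5.69 CPM in WT CXCR6+ libraries and no counts in either WT SLAMF6+ library, at least 9.89-fold higher, background included, against a floor of 3 counts per library. Before scaling it read 18.1 CPM in WT CXCR6+ replicate 1, where background would give 16.8 CPM, and 19.7 CPM in replicate 2, where it would give 0.493 CPM. Of 39 lists, 5 were called. Stem-like and memory genes were lower in 16 of 20 (median -0.57, adjusted p = 1.36e-07; adjusted p = 0.453 with an estimated correlation), 4 of them adjusted over the list alone (Slamf6, Tcf7 at -1.77 ± 0.53, Foxp1 at -1.61 ± 0.45 and Izumo1r at -1.48 ± 0.52). TFH-type genes (10 of 11 lower, median -0.83, adjusted p = 3.44e-05; adjusted p = 0.453 with an estimated correlation), immediate early genes (13 of 17 lower, median -0.48, adjusted p = 0.00106; adjusted p = 0.999 with an estimated correlation) and T cell receptor response genes (13 of 20 lower, median -0.26, adjusted p = 0.0385; adjusted p = 0.999 with an estimated correlation) were lower, and none of their members passed adjusted over the list alone. The TH17 program was higher in 17 of 21 (median 0.37, or 0.20 with the 4 genes whose WT SLAMF6+ libraries or WT CXCR6+ libraries were all at 0 set to their bound, adjusted p = 0.0385; adjusted p = 0.999 with an estimated correlation), with 2 adjusted over the list alone.

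None of these 5 WT lists was called when the correlation between genes was estimated. Without Slamf6 the stem-like list kept its call (adjusted p = 3.66e-06; adjusted p = 0.775 with an estimated correlation). It was lost without WT CXCR6+ replicate 1 (adjusted p = 0.177), as were the TFH, immediate early and receptor response lists (0.539, 0.687 and 0.0839). Without WT SLAMF6+ replicate 2 the last 3 were lost too (0.0575, 0.184 and 0.585), as was the TH17 program (0.184). That program was also lost without WT SLAMF6+ replicate 1 (0.0873) or WT CXCR6+ replicate 2 (0.391), and with the background covariate. The 4 lower lists were lost in the low-background libraries, which hold only replicate 2 of WT CXCR6+, and kept with the covariate. Over 10 alternatives the direction of the immediate early and receptor response lists reversed in 2 each, and that of the TH17 program in 1. No single gene changed between the WT subsets by edgeR's quasi-likelihood test (0 of 24195, with 1728 at an unadjusted p under 0.05). DESeq2 called 33, limma's voom 0 and edgeR with the background covariate 135, of which the subsets did not overlap in 122. Chance gives no overlap for 33.3% of unselected genes, but these were selected on the same libraries, so it is no separate support. The WT CXCR6+ libraries had the largest ratio of receptor-gene densities within a group (2.64 and 0.0775 CPM per kb). More genes passed without either of them, in fits that leave 1 library in that group. The median log2 change of all genes was 0.27 in this comparison.

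Between genotypes, 14 of the 16 genes called in DKO cells had the same sign in WT cells, the sort genes Cxcr6 and Slamf6 among them. The exceptions were Ccl17 (1.49 ± 1.15 in WT) and Ccdc28b (0.97 ± 0.65 in WT). Over the alternatives these WT changes were 0.464 or more for Ccl17 and 0.416 to 1.81 for Ccdc28b, without a call. Across all 24195 genes, which are not independent replicates, the subset changes in WT and DKO correlated with r = 0.116. That value had the opposite sign without WT CXCR6+ replicate 1 (-0.129) and rose to 0.359 over genes with a mean of at least 10 CPM. With the background covariate 33 genes passed in both genotypes, all in the same direction, 7 higher and 26 lower in CXCR6+ cells. Independent calls would give 0.247 and 0.329, but both comparisons come from 1 fit. The 33 include Cxcr6 and Slamf6, whose direction was set by the sort. Among them were Il1r2 and Cd93 (3.26 in WT and 2.60 in DKO), a lectin-like receptor, on the CXCR6+ side, and Il2, Pou2af1, Tcf7, Foxp1, Izumo1r, Ighm, Jund, Egr1 and Ccl22 on the SLAMF6+ side, all chosen after their values were seen. The genotype by subset interaction called 0 genes by edgeR (1049 at an unadjusted p under 0.05, smallest adjusted p = 0.928), 1 by DESeq2 and 0 by limma's voom, and no list. It called more without either WT CXCR6+ library, in fits that leave 1 library in that group. With the covariate it called 6 genes, of which Ccl17 had the smallest p (-6.56 ± 1.09). Ccl17 read 8.56 ± 2.73 CPM in WT CXCR6+ and 2.91 ± 4.11 CPM in WT SLAMF6+ cells, the reverse of the order in DKO cells.

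From WT to DKO, Il17a fell in both subsets and genes of the Y chromosome rose. Uty, a histone demethylase gene, read 39.0 ± 4.36 CPM in DKO CXCR6+ and 38.6 ± 8.90 CPM in DKO SLAMF6+ libraries (n = 4 each) and no counts in any WT library, at least 39.0-fold and 19.7-fold higher, background included, against a floor of 3 counts per library (adjusted p = 1.62e-05 and 0.000118). Ddx3y, an RNA helicase gene, rose by 8.10 ± 0.85 in CXCR6+ cells (adjusted p = 8.21e-06) and by 6.01 ± 0.75 in SLAMF6+ cells (adjusted p = 0.000118). Eif2s3y, a translation factor gene, rose by 5.70 ± 0.80 (adjusted p = 0.00101) and 8.81 ± 1.10 (adjusted p = 0.000118). Kdm5d, also without counts in WT libraries, was at least 20.7-fold higher in CXCR6+ cells (adjusted p = 0.0166) and at least 12.6-fold higher in SLAMF6+ cells without passing (adjusted p = 0.0573). These bounds include background. Over 16 alternatives Kdm5d lost its call in 6 in CXCR6+ cells, and over 16 gained it in 6 in SLAMF6+ cells. Before scaling Kdm5d read 5.53 to 38.6 CPM in DKO CXCR6+ libraries, where background would give a gene of its length 5.197 to 48.6 CPM. That estimate comes mostly from autosomal genes, so it is high for a Y-linked gene, which has a single copy. Uty was above background in all 8 DKO libraries (by 23.0 and 28.5 CPM on average in CXCR6+ and SLAMF6+ cells). Xist, the transcript of the inactive X chromosome, read 45.9 to 117 CPM in WT and 1.91 to 21.6 CPM in DKO libraries, a change of -2.83 ± 0.65 and -3.03 ± 0.65 that did not pass (adjusted p = 0.642 and 0.237). In WT CXCR6+ replicate 1 it read 54.3 CPM before scaling, where background would give 47.3 CPM. As a list, the 5 sex-linked genes were higher in DKO cells (medians 8.10 and 8.81, or 5.29 and 4.30 with Uty and Kdm5d at their bounds; adjusted p = 1.69e-34 and 3.54e-20), which held with an estimated correlation and without any 1 library. Genotype and these genes changed together in all 12 libraries, so a genotype difference elsewhere could not be parted from a difference in sex.

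In CXCR6+ cells 5 genes differed between genotypes, Il17a lower and the 4 Y-linked genes higher, with 733 of 24195 at an unadjusted p under 0.05. DESeq2 called 7, limma's voom 1 and edgeR with the background covariate 84, of which the genotypes did not overlap in 21. Chance gives this for 13.3% of genes not selected on these libraries. The count was higher without either WT CXCR6+ library, in fits that compare DKO cells with 1 WT library. Beside the sex-linked list, 8 lists were called, and 1 member passed over all genes in the cytokine and TH17 lists, which was Il17a in each. Both lists hold the deleted genes Il17a and Il17f, so part of their fall was set by the knockout. Neither list was tested without these genes. T cell cytokine genes were lower in 17 of 29 (median -0.27, adjusted p = 5.16e-05; adjusted p = 0.436 with an estimated correlation). TH2-type genes were lower in 7 of 9 (median -0.81, adjusted p = 0.00144; adjusted p = 0.0848 with an estimated correlation), with Il13, a TH2 cytokine, at 492 ± 238 CPM in WT and 254 ± 68.1 CPM in DKO cells, and Gata3, the TH2 regulator, at 307 ± 97.1 and 175 ± 51.5 CPM, neither past the threshold. IL-17 receptor and response genes were lower in 9 of 14 (median -0.17, adjusted p = 0.00722; adjusted p = 0.1399 with an estimated correlation). Without WT CXCR6+ replicate 2 these 3 lists were lost (adjusted p = 0.241, 0.925 and 0.971). With the background covariate the cytokine and IL-17 receptor lists were lost and the TH2-type list was kept.

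B cell markers were also called lower in DKO CXCR6+ cells (median -0.43, adjusted p = 0.00795; adjusted p = 0.296 with an estimated correlation; 2 adjusted over the list alone), but Igkc (-3.46 ± 0.94) stood at 122 CPM before scaling in WT CXCR6+ replicate 1 and at 3.87 CPM in replicate 2. Without replicate 1 its change was 0.07, and the list was lost (adjusted p = 0.557), as it was without DKO CXCR6+ replicate 5 (0.0819). The TH17 program (median -0.01, adjusted p = 0.0135), glycolysis (median -0.18, adjusted p = 0.0203) and regulatory T cell genes (median -0.28, adjusted p = 0.0393) were called lower and cytotoxicity genes higher (median 0.32, adjusted p = 0.0412), each with an adjusted p between 0.436 and 0.894 with an estimated correlation. The first 3 were lost without DKO CXCR6+ replicate 4 or 5 (adjusted p from 0.0592 to 0.855). The TH17 and regulatory lists were lost without WT CXCR6+ replicate 2 as well (adjusted p = 0.207 and 0.957), and cytotoxicity without WT CXCR6+ replicate 1 (0.0654) or DKO CXCR6+ replicate 3 or 6 (0.192 and 0.221). With the background covariate the TH17, glycolysis and regulatory lists were lost, and the glycolysis median was 0.25, so its sign was not settled. The B cell and cytotoxicity lists were lost in the low-background libraries and kept with the covariate. Over 10 alternatives the directions of the cytotoxicity and glycolysis lists reversed in 2 each. Those of the TH17, regulatory and T cell cytokine lists reversed in 1 each. The signs of these lists were not settled either. Klrc1, an inhibitory NKG2 receptor gene chosen after its values were seen, read 29.0 ± 12.3 CPM in DKO and 3.87 ± 4.24 CPM in WT CXCR6+ cells. It did not pass with all libraries (2.84 ± 0.90, adjusted p = 1) and passed with the covariate (3.45 ± 0.73). Ccl3, a chemokine of activated T cells chosen the same way, did not pass either (0.79 ± 0.56, adjusted p = 1) and passed with the covariate (1.65 ± 0.28), although the genotypes overlapped.

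In SLAMF6+ cells 4 genes differed between genotypes, Il17a, Uty, Ddx3y and Eif2s3y, with 1581 at an unadjusted p under 0.05. The same 4 were called in CXCR6+ cells, 3 higher and 1 lower. They are a deleted gene and Y-linked genes, which follow genotype in all libraries. Their sharing is therefore no evidence of a genotype response common to the subsets. DESeq2 called 18, limma's voom 3 and edgeR with the background covariate 83 (77 without overlap), and the count stayed between 4 and 5 without any 1 library. Chemokine genes were higher in 9 of 9 (median 1.77, or 0.90 with genes at 0 in WT set to their bound; adjusted p = 0.00128; adjusted p = 0.213 with an estimated correlation), and the call was lost without WT SLAMF6+ replicate 1 (adjusted p = 0.199). Adjusted over the list alone 2 passed: Ccl5, the RANTES gene (293 ± 266 CPM in DKO against 73.3 ± 44.4 CPM in WT, 1.99 ± 0.65; DKO SLAMF6+ replicate 4 read 692 CPM and the others 157 to 165, and without it the change was 1.12), and Ccl20, the CCR6 ligand gene, which read 15.8 ± 12.6 CPM in DKO and no counts in WT cells, at least 8.11-fold higher. T cell cytokine genes were called lower (adjusted p = 0.0449, and 0.961 with an estimated correlation) although their median, 0.07, and mean, 0.12, were positive. The call is relative to the other tested genes. T cell cytokine genes include the deleted Il17a and Il17f and were not tested without them. Il17a was their 1 member past the threshold, and the call was lost without WT SLAMF6+ replicate 2 (0.745) or DKO SLAMF6+ replicate 3 or 5 (0.252 and 0.115), with the background covariate and in the low-background libraries. The median log2 change of all genes in this comparison was 0.36, and 0.24 with RLE scaling. Across genes the genotype changes in the subsets correlated with r = 0.105, and with 0.252 without WT CXCR6+ replicate 1.

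The T cell receptor beta variable segment Trbv16, which has the most counts of all beta variable segments here, held 89.4% to 99.4% of such counts in every library. The lowest share was 741 of 829 counts in WT CXCR6+ replicate 1 (Clopper-Pearson 95% interval 87.1% to 91.4%), and the highest was 12545 of 12626 counts in WT CXCR6+ replicate 2 (99.2% to 99.5%). Intervals and floors given here cover counting error only. Of the 39 lists, 21 were called in none of the 5 comparisons. They included the cell cycle lists (24 S phase and 26 G2 and M phase genes, medians between -0.15 and 0.27 over the comparisons), oxidative phosphorylation (33 genes, medians between -0.09 and 0.11), cholesterol biosynthesis, inhibitory receptors and exhaustion genes, and the 7 tested neighbours of the Il17 locus on chromosome 1 (medians 0.49 and 0.48 from WT to DKO in CXCR6+ and SLAMF6+ cells, adjusted p = 0.991 and 0.931).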

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

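The tests of background by group, of X copy number as a mark of sex, of Il17a against the genotype labels and of B cell genes against Pou2af1, Irf8 and Pou2f2 were chosen only after their results were seen, and the background covariate is an alternative added after the data were seen. In 13 of 150 sets of 4 DKO libraries, 1 library stood apart from the other 3, measured as its gap to the nearest divided by the whole range, and chance flags about 1 in 20 groups. DKO SLAMF6+ replicate 4 was the high library for Ccl5 (692 CPM against 157 to 165, ratio 0.985), Il2 (245 against 104 to 119, ratio 0.895), Dgkk (146 against 75.3 to 84.2, ratio 0.874), Jchain (71.6 against 9.81 to 18.2, ratio 0.864), Prss2 (88.7 against 39.4 to 46.5, ratio 0.856) and Igkc (470 against 25.5 to 96.6, ratio 0.840). DKO SLAMF6+ replicate 6 was high for Crtam (105 against 51.1 to 59.1, ratio 0.852) and Il13 (202 against 134 to 144, ratio 0.843). Among DKO CXCR6+ libraries, replicate 6 was high for Ccdc28b (12.4 against 9.46 to 9.85, ratio 0.869) and Rbp1 (94.6 against 43.7 to 51.1, ratio 0.854), replicate 5 for Cxcl3 (36.4 against 16.7 to 19.95, ratio 0.834), and replicate 3 for Ifng (264 against 57.5 to 91.3, ratio 0.836). Replicate 3 also had counts on 22781 genes where the others had 39303 to 40916 (ratio 0.911). By edgeR's interaction test 0 genes differed between the genotypes in their subset effect (1049 at an unadjusted p under 0.05). DESeq2 called 1, voom 0 and edgeR with the background covariate 6. EdgeR called more without either WT CXCR6+ library, in fits that leave 1 library in that group.

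Receptor genes of smell, which are silent in T cells, carried counts, up to 3.20 CPM per kb in DKO CXCR6+ replicate 4. Among 224 X-linked and 2425 autosomal genes without counts in the cleanest library of each genotype, density on chromosome X over autosomes was 0.554 in the other 7 DKO libraries pooled (95% bootstrap interval 0.462 to 0.651). It was 1.09 in the other 3 WT libraries pooled (0.858 to 1.37), a ratio of 0.509 (0.420 to 0.625), but single WT libraries gave 0.745 to 1.18 (DKO libraries 0.461 to 0.625), 914 of the 1208 WT counts on X came from WT CXCR6+ replicate 1, and without it the values were 0.887 (0.611 to 1.19) and 0.625 (0.480 to 0.874). Genomic DNA would leave these ratios if DKO cells had a single X chromosome and WT cells a pair, while a part of subset or genotype stays open: 0 of 4 comparisons had groups without overlap in density, but 3 have too few libraries for an exact p under 0.05. The background did not by itself produce the DKO subset calls, since 16 of 16 kept their direction and threshold with it as a covariate. Of 35 splits of the 8 DKO libraries 1, the real one, gave as many calls (16, highest other 0). With the covariate it was likewise 1 of 35 (207, highest other 9). The other splits mix the sorted subsets within a group, which widens the spread, and 35 splits are few. The splits therefore do not exclude chance, for the number or for each gene.

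The Y-linked genes were read in every DKO library and Xist mainly in WT libraries. Summed Y-linked CPM were 248 to 368 in DKO and 0 to 7.87 in WT libraries. The ratio of 0.509 (0.420 to 0.625; without WT CXCR6+ replicate 1 0.625, 0.480 to 0.874) between genotypes in background density on chromosome X over autosomes is what a single X in DKO cells and a pair in WT cells would leave, a test that bears on genomic DNA and on sex together. A mislabelled genotype is argued against, since 0 of 12 libraries had Il17a on the wrong side of 50 CPM for their label (93.8 to 936 CPM in WT, 0.213 to 5.93 CPM in DKO). The sex of donors and cells is not given in the sources used here, so effects of sex and of genotype cannot be parted by this design, and a genotype difference in other genes could be either (limma's voom called 1 gene in CXCR6+ cells).

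Immunoglobulin genes were read in SLAMF6+ libraries of both genotypes. Background is argued against as the cause, since with it as a covariate Ighm changed by -3.84, against -4.31 without. B cells that carry surface and MHC class II genes are argued against as the main source of Pou2af1, Irf8 and Pou2f2. Less background, 8 such genes were a median of 2.90 CPM higher in DKO SLAMF6+ than in DKO CXCR6+ libraries (up to 3.87 without any 1 library). Pou2af1, Irf8 and Pou2f2 were at least 30.1 CPM higher. Of the 8, Cd74 (20.8), H2-Eb1 (9.55), Cd79b (5.93), Cd19 (4.34), Cd79a (1.46) and H2-Aa (1.10) were higher. Ms4a1 (-0.726) and H2-Ab1 (-14.6) were lower. A smaller part from B cells is therefore not excluded. The 8 genes cannot show cells poor in them, so antibody-secreting cells were not tested as a source of Pou2af1, Irf8 and Pou2f2. For the immunoglobulin genes, B cells and antibody-secreting cells remain open. The median change of the 6 other tested B cell and plasma cell markers was -1.01, with members both ways. Cd79a was not above its background in the DKO SLAMF6+ libraries together (-0.0351% of Ighm). Antibody-secreting cells, rich in immunoglobulin and poor in Cd79a, could leave this. The cells were sorted as CD4+, a gate that should remove such cells, and the hosts lack RAG2 and cannot make B cells of their own, so such cells or their RNA would have to come with the transfer or from handling, which no test here separates.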

How the results depend on the processing

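The background covariate, the low-background libraries, the mean of at least 10 CPM, their combinations and the lists without the sorted genes (which changed no count of called lists) were chosen only after the data were seen. Depth and background limit these results: a library with 1347044 counts reads a floor of 3 counts as over 2 CPM, and in the libraries with most background long genes at low level cannot be told from it. Whether replicate numbers pair the samples was not settled, so the block is an alternative only. Libraries that share a number correlated, after removal of group means, at 0.155, 0.155, -0.362, -0.299, 0.313 and 0.418 (numbers 1 to 6). Numbers 1, 2 and 6 were the best match within the partner group. With 2 libraries per WT group the WT values are equal by construction. Background density differs between libraries that share a number, so low correlations do not exclude pairing. Where a value below changed, the cause was not tested, except that leaving out genes or libraries changes what can be called. Fits without 1 WT library leave 1 library in that group, and the low-background libraries hold only replicate 2 of WT CXCR6+. Calls and counts of such fits for that group rest on the spread of the other groups. Of the alternative values of main results, 232 kept direction and side of the threshold or stayed near, 74 counts or correlations moved, 16 gained and 14 lost a call and 5 reversed. Of those of single genes, 1455 were the same, 304 gained and 89 lost a call, and 1 reversed. That was Igkc from WT to DKO in CXCR6+ cells (-3.46), with a range of -4.39 to 0.068 without 1 library. It reversed without WT CXCR6+ replicate 1 and passed without WT CXCR6+ replicate 2.

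Genes changed between the WT subsets (0) numbered 1 with RLE size factors, 33 with DESeq2, 4 with no filter, 5 with the replicate block, 135 with the background covariate, 266 in the low-background libraries, 116 with covariate and mean filter, and 192 with block and covariate. Without 1 library there were 0 to 120 (120 without WT CXCR6+ replicate 1, 113 without WT CXCR6+ replicate 2). Between the DKO subsets (16) they numbered 126 with DESeq2, 32 with voom, 25 with no filter, 207 with the covariate, 91 in the low-background libraries, 27 with the mean filter, 253 with covariate and mean filter, and 194 with block and covariate. Leave-one-out counts were 1 to 17. The count was 1 without DKO SLAMF6+ replicate 4 and 2 without DKO CXCR6+ or DKO SLAMF6+ replicate 6. It was 7, 10 and 8 without DKO CXCR6+ replicates 3, 4 and 5, and 8 without DKO SLAMF6+ replicate 5. From WT to DKO in CXCR6+ cells (5) they numbered 1 with voom, 3 with only the compared libraries, 1 without receptor segments, mitochondrial, ribosomal protein and sex-linked genes, 84 with the covariate, 19 in the low-background libraries, and 18 with covariate and mean filter. Without 1 library there were 4 to 327 (327 and 55 without WT CXCR6+ replicates 1 and 2). In SLAMF6+ cells (4) they numbered 18 with DESeq2, 9 with no filter, 8 with only the compared libraries, 1 without those gene classes, 83 with the covariate, 250 in the low-background libraries, and 26 with covariate and mean filter. Leaving out 1 library gave 4 to 5. The interaction (0) gave 1 with DESeq2, 2 with no filter, 6 with the covariate, 36 in the low-background libraries, and 24 with block and covariate. Single removals gave 0 to 122 (122 and 23 without WT CXCR6+ replicates 1 and 2).

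Il17a kept its direction and call in every alternative (-8.68 to -6.57 in CXCR6+ and -6.57 to -4.92 in SLAMF6+ cells without 1 library). Il17f in CXCR6+ cells (-4.38) passed with the covariate (-6.55), in the low-background libraries (-8.07) and without WT CXCR6+ replicate 1 (-4.86). Its range was -5.08 to -3.58 without 1 library. In SLAMF6+ cells Il17f (1.59) reversed in the low-background libraries (-1.82). Cxcr6 between the WT subsets (3.85) passed with DESeq2 (3.76), no filter (3.89), the replicate block (4.255), the covariate (3.51), the low-background libraries (4.50), covariate and mean filter (3.56) and block with covariate (4.04). It ranged from 2.68 to 10.42 without 1 library and passed without WT CXCR6+ replicate 1 (4.49). The 10.42 is over a library with 0 counts and set by the prior count, so without WT SLAMF6+ replicate 2 the change is only bounded, at 4.498 or more against a floor of 3 counts. Slamf6 there (-2.14) passed with the covariate (-2.49), in the low-background libraries (-4.89), with covariate and mean filter (-2.47) and with block and covariate (-2.70). It ranged from -4.95 to -1.19 without 1 library and passed without WT CXCR6+ replicate 1. Between the DKO subsets, Cxcr6 ranged from 2.62 to 2.93 and Slamf6 from -3.18 to -2.74 without 1 library. Cxcr6 kept its call only without DKO CXCR6+ replicate 4. Slamf6 lost its call without DKO CXCR6+ replicate 3 or 6, or DKO SLAMF6+ replicate 4, 5 or 6. It also lost it with RLE size factors (-2.79) and the mean filter (-2.80).

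The correlation of subset changes between genotypes (0.116) was -0.187 in the low-background libraries, -0.0315 with block and covariate, 0.359 with the mean filter and -0.129 to 0.167 without 1 library (-0.129 without WT CXCR6+ replicate 1). That of genotype changes between subsets (0.105) was -0.177 in the low-background libraries and 0.0163 to 0.252 without 1 library (0.252 without WT CXCR6+ replicate 1). Lists called between the WT subsets (5) numbered 0 with the estimated correlation, and 16 in the low-background libraries. Without 1 library there were 1 to 18 (16 and 18 without WT CXCR6+ replicates 1 and 2, 9 and 1 without WT SLAMF6+ replicates 1 and 2). Between the DKO subsets (12) they numbered 2 with the estimated correlation, 7 with block and covariate and 10 to 17 without 1 library. From WT to DKO in CXCR6+ cells (9) they numbered 1 with the estimated correlation, and 15 with the covariate. Leave-one-out counts were 6 to 23 (23 and 21 without WT CXCR6+ replicates 1 and 2, 15 without DKO CXCR6+ replicate 3). In SLAMF6+ cells (3) they numbered 1 with the estimated correlation and 10 in the low-background libraries. Leaving out 1 library gave 2 to 10 (10 without DKO SLAMF6+ replicate 6, 5 without replicate 4). The interaction (0) gave 2 lists with the covariate, 15 in the low-background libraries, and 2 with block and covariate. Single removals gave 0 to 19 (18 and 19 without WT CXCR6+ replicates 1 and 2, 1 without DKO CXCR6+ replicate 3 or 4 or DKO SLAMF6+ replicate 6).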

Other observations

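Several genes, all outside the fixed lists except Spp1 of the cytokine list, followed the subsets in both genotypes once background was in the model. All were chosen after their values were seen. Zfp36l1, which degrades messenger RNAs, averaged 27.0 ± 17.2 CPM in WT CXCR6+ and 24.99 ± 17.2 CPM in DKO CXCR6+ libraries against 87.4 ± 2.20 and 87.5 ± 14.3 CPM in the SLAMF6+ libraries (SD, n = 2 in WT and 4 in DKO). Sox4, a transcription factor, read 7.75 ± 2.31 and 12.6 ± 4.02 CPM in CXCR6+ against 49.1 ± 31.6 and 37.8 ± 15.3 CPM in SLAMF6+ cells. Spp1, the osteopontin gene, read 147 ± 14.8 and 166 ± 114 CPM against 404 ± 31.0 and 298 ± 66.5 CPM, with overlap between the DKO subsets. Cd9, a tetraspanin gene, and S100a6, a calcium-binding protein gene, were also lower in CXCR6+ cells (Cd9 -1.47 in WT and -0.94 in DKO, S100a6 -1.11 and -0.88, with overlap between the DKO subsets in S100a6). On the CXCR6+ side Gpr141, an orphan receptor gene, read 32.9 ± 17.1 and 33.7 ± 6.52 CPM against 2.61 ± 0.396 and 9.87 ± 5.64 CPM, and Cd93 35.6 ± 13.8 and 24.0 ± 10.6 CPM against 3.20 ± 4.52 and 4.03 ± 2.85 CPM. None of these passed in either genotype by edgeR's test with all 12 libraries and no covariate. Some passed in other alternatives without it: Zfp36l1 between the DKO subsets in 6, Cd9, Sox4 and S100a6 between the DKO subsets and Sox4 and Gpr141 between the WT subsets with DESeq2, and Cd93 in the low-background libraries in both genotypes. S100a6 between the DKO subsets passed with limma's voom too, and Cd93 and Gpr141 between the WT subsets passed without WT CXCR6+ replicate 1 and replicate 2, respectively. Before scaling, Sox4 exceeded what background would give a gene of its length in only 1 of 2 WT and 2 of 4 DKO CXCR6+ libraries, and in all SLAMF6+ libraries. Cd93 exceeded it in 2 of 2 WT and 3 of 4 DKO CXCR6+ libraries, and in 1 of 2 WT and 1 of 4 DKO SLAMF6+ libraries. Gpr141 exceeded it in 0 of 2 WT SLAMF6+ libraries and in all others.

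Il24, a cytokine gene of the IL-10 family, averaged 321 ± 241 CPM in WT CXCR6+ and 108 ± 7.22 CPM in WT SLAMF6+ cells, and 235 ± 127 and 86.0 ± 38.0 CPM in DKO cells. Il1r1 read 27.5 ± 5.67 CPM in DKO CXCR6+ and 10.9 ± 5.48 CPM in DKO SLAMF6+ cells. The WT SLAMF6+ libraries held no counts of it (adjusted p = 0.0922 from WT to DKO). Before scaling, DKO SLAMF6+ libraries exceeded what background would give a gene of its length by only 3.73 CPM on average, in 3 of 4, so how far it differed was not settled. Klrc1 read 14.6 ± 3.37 CPM in DKO and 0.721 ± 1.02 CPM in WT SLAMF6+ cells. Il2 read higher in DKO than in WT CXCR6+ cells (23.8 ± 9.44 against 9.44 ± 9.64 CPM, log2 change 1.28 ± 0.56) without passing (adjusted p = 1).

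The subset difference may be shared between the genotypes and hidden in WT cells by background. The test with background as a covariate called 135 genes between the WT subsets and 207 between the DKO subsets, with 33 shared, each in the same direction in both genotypes (7 higher and 26 lower in CXCR6+ cells), which is consistent with this. The covariate was chosen on the same libraries, and the sort genes Cxcr6 and Slamf6 are among the 33. Of the 207 genes called in DKO cells 180 had the same sign in WT cells, and of the 135 called in WT cells 99 had the same sign in DKO cells. Over all genes the subset changes of the genotypes correlated at only 0.0236 with the covariate, and at 0.176 over genes with a mean of at least 10 CPM.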
